A study of Mus musculus with 28 samples.

How the data were processed

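RNA of mouse (C57BL/6) cortex and hippocampus was sequenced in 28 libraries, 25 of them from single neurons and 3 from pieces of hippocampal tissue. Per the labels' protocols, cultured neurons had grown on coverslips for 7 to 9 days, and the tissue came from acute coronal slices of mice 8 to 10 days old. The series title also names human brain, and every library analysed here is labelled mouse. TIVA stands for transcriptome in vivo analysis: a light-activated tag enters cells, a laser opens it in 1 chosen cell, and the opened tag binds the polyadenylated RNA of that cell for capture. Per the labels' protocols, cultured neurons were loaded with 10 µM tag for 15 min and the laser ran at 30% power, and tissue neurons were loaded with 30 µM tag for 90 min and the laser ran at 80% power. Both TIVA protocols in the labels have the imaged field around the photolysed cell aspirated before capture. The other single neurons were drawn up with a glass pipette. All samples went through 3 rounds of linear amplification by in vitro transcription and were prepared with TruSeq for paired-end Illumina sequencing, per the labels' protocols.

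The authors deposited 1 table of whole-number read counts per library, and their processing notes name CASAVA 1.8.1, HTSeq without a version, and the mouse genome build mm9. The aligner, the HTSeq overlap mode and the use of strand are not given in the sources used here, so reads of overlapping or antisense features, and reads shared by near-identical copies, could not be told apart. The rows are 28661 features named by UCSC known-gene identifiers, and 11967 of them join several isoform identifiers in a single name. The files end in 5 HTSeq summary lines, of which 3 are 0 in all 28 libraries. The no-feature line held 15.8% to 81.1% of all counted reads and the ambiguous line 0.589% to 10.9%. These lines name no gene and were left out of library sizes.

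Gene names could not be attached. The files do not pair the identifiers with symbols, and 0 of the 55419 single identifiers matched a table given with the data, whose annotation is of a later build. The 24 lists of neuronal, glial and other genes fixed before the data were examined were for this reason not used, nor were the marker shares, and no coordinates were taken from the later build. Features are therefore reported as identifiers. The rule for named features, also fixed before the data were examined, took features with a group mean of 20 CPM (counts-per-million, each count scaled to the assigned reads of its library) or more and 10 or more reads in every library of the higher group. Every library of the higher group also had to lie above every library of the other, and features were ranked by the difference in mean log2(CPM + 10). It allowed 10 names per direction in the main comparisons and 3 in the others. Without symbols, only the first 2 in each direction of a single comparison are printed, that of hippocampal tissue TIVA with hippocampal cultured TIVA neurons, a restriction made after the identifiers were seen.

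Libraries were grouped by the source name in the labels: region, culture or tissue, and means of collection. The hippocampal tissue neurons with a pipette source name and no treatment carry a protocol text that describes TIVA capture, and the protocol text of the cortical tissue TIVA neurons mentions the hippocampal CA1 field. In both cases the source name was followed. Groups held 2 to 5 libraries, and 11 comparisons between them were made. Replicate numbers follow the order of the records and pair no libraries. For each pair of libraries of a group the counts were compared by a chi-square statistic. The lowest value per degree of freedom was 48.6, between libraries 2 and 3 of the hippocampal cultured TIVA neurons, so no pair was within sampling noise and none was merged.

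No test was run and no p-value is given. Each of the 25 single-neuron libraries is 1 cell and the labels name no animal or culture, so cells are not replicates and each group counts as 1 sample. Differences are given by size beside the standard deviation (SD) or range over cells, and n is the number of libraries. The labels give no sequencing date or library batch, so a batch and a group cannot be told apart.

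Assigned reads ranged from 5.30 M to 59.0 M per library (M for mega, the scale of CPM), and 3 reads, the upper limit that a count of 0 allows, were worth 0.0508 to 0.567 CPM. All libraries were thinned once, with a fixed seed, to 5.30 M reads, the smallest total, and a feature with 1 or more reads was detected. Similarity was Pearson's r of log2(CPM + 10) over the 10694 features with a mean of 5 CPM or more. Those correlations run across features, which are not independent replicates. The gap between groups was the mean of both within-group median correlations minus the median correlation between the groups. The on-off share was the percentage of features at 50 CPM or more in a library that lay below 1 CPM in another library of its group, at the common depth, over ordered pairs. The share of bulk features missing was the percentage of the 2565 features at 50 CPM or more in all 3 bulk libraries that lay below 1 CPM in a single-neuron library. Differences of features were differences of mean log2(CPM + 10), each library weighted equally, among features with a mean of 5 CPM or more in at least 1 group of the comparison. The pseudocount of 10 CPM understates differences of low features. Summed counts carry exact Poisson intervals and shares of reads Wilson intervals, both at 95%. The widest Wilson interval of a no-feature share was 0.0581 percentage points. Amplified reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

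Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for alternative library scalings only. The steps were tested on simulated data drawn from the real means and library sizes of hippocampal tissue TIVA and cultured TIVA neurons, over 28661 features. Features raised 4-fold (log2 of 2.00) came back with a median log2 difference of 1.82, and those raised 2-fold (1.00) with 0.79. In this check the median difference over measured features was subtracted, a step not used for the reported differences. For the on-off share, 9.99% of features were silenced by design and the share was recovered as 9.99%. The silencing itself fixed this value, so it checks the counting step only. It does not show how sampling noise, thinning or dropout between libraries affects the share. For the correlation between both comparisons with bulk tissue, 100 simulations of unchanged groups against the same bulk libraries gave the value due to the shared libraries.

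Alternatives fixed before the data were examined were pseudocounts of 1 and 50 CPM, TMM and DESeq2 scaling, scaling without the 50 most abundant features, thinned counts, no filter or a filter of 20 CPM, medians, summed counts, unthinned detection, detection at 5 or more reads, another thinning draw, an on limit of 20 CPM, Spearman correlation and leaving out each library. Added after seeing the data were detection at 10 CPM or more and at 50 CPM or more, the latter also over the reads outside the 50 most abundant features, detection without those features, the share of bulk features missing, and the correlations between the tissue and culture differences of the TIVA neurons of both regions and between the region differences of both means of capture.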

Results

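The series measured which transcripts single neurons of mouse cortex and hippocampus contain when they are sampled in culture or in living tissue slices. Cultured cortical neurons gave 4 libraries by pipette and 4 by TIVA. Cultured hippocampal neurons gave 3 by pipette and 4 by TIVA. Hippocampal tissue gave 3 neurons by pipette, 5 by TIVA and 3 bulk libraries, and cortical tissue gave 2 neurons by TIVA. Bulk tissue holds all cell types of the region, neurons and glia together. The series design text names cortical and hippocampal neurons collected by pipette and by TIVA, so the comparisons address the means of capture, the setting (tissue or culture), single cells against bulk tissue, and the brain region.

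Library depth differed between groups. Median assigned reads were 31.7 M (mega) in bulk tissue (26.7 to 59.0 M), 26.5 M in hippocampal tissue TIVA neurons (24.1 to 33.4 M) and 20.6 M in hippocampal cultured TIVA neurons (9.13 to 26.2 M). Cultured cortical pipette neurons had 12.3 M (11.2 to 25.7 M), cultured cortical TIVA neurons 11.3 M (9.77 to 15.5 M) and cultured hippocampal pipette neurons 11.3 M (9.89 to 32.9 M). Hippocampal tissue pipette neurons had 7.83 M (6.64 to 11.6 M), and the cortical tissue TIVA neurons had 7.89 and 5.30 M. Detection was therefore compared at a common 5.30 M reads. No test was run, because each neuron is 1 cell and the labels name no animal or culture, and all differences are given beside the spread over libraries.

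With features counted from 1 read at the common depth, fewer were detected in neurons from tissue than in cultured neurons or bulk tissue. There a hippocampal tissue neuron held a median of 9822 features by TIVA (SD 729, n = 5) and 9231 by pipette (SD 397, n = 3), and a cortical tissue neuron held 7363.5 (SD 739, n = 2). Bulk hippocampus held 16528 (SD 254, n = 3). Cultured neurons held 18853 in hippocampus by pipette (SD 1883, n = 3), 15505 in hippocampus by TIVA (SD 1544, n = 4), 13891 in cortex by pipette (SD 1342, n = 4) and 17675.5 in cortex by TIVA (SD 2038, n = 4). The highest of the tissue neurons, at 10765 features, lay below the lowest cultured neuron, at 12340. The order was not the same at 50 CPM or more, where hippocampal tissue neurons held a median of 3819 features by TIVA and 3199 by pipette, bulk tissue 3776, hippocampal cultured TIVA neurons 2501 and hippocampal cultured pipette neurons 3870. With CPM taken over the reads outside the 50 most abundant features, the tissue minus culture difference of hippocampal TIVA neurons at this limit was −428.

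**Figure D1:**
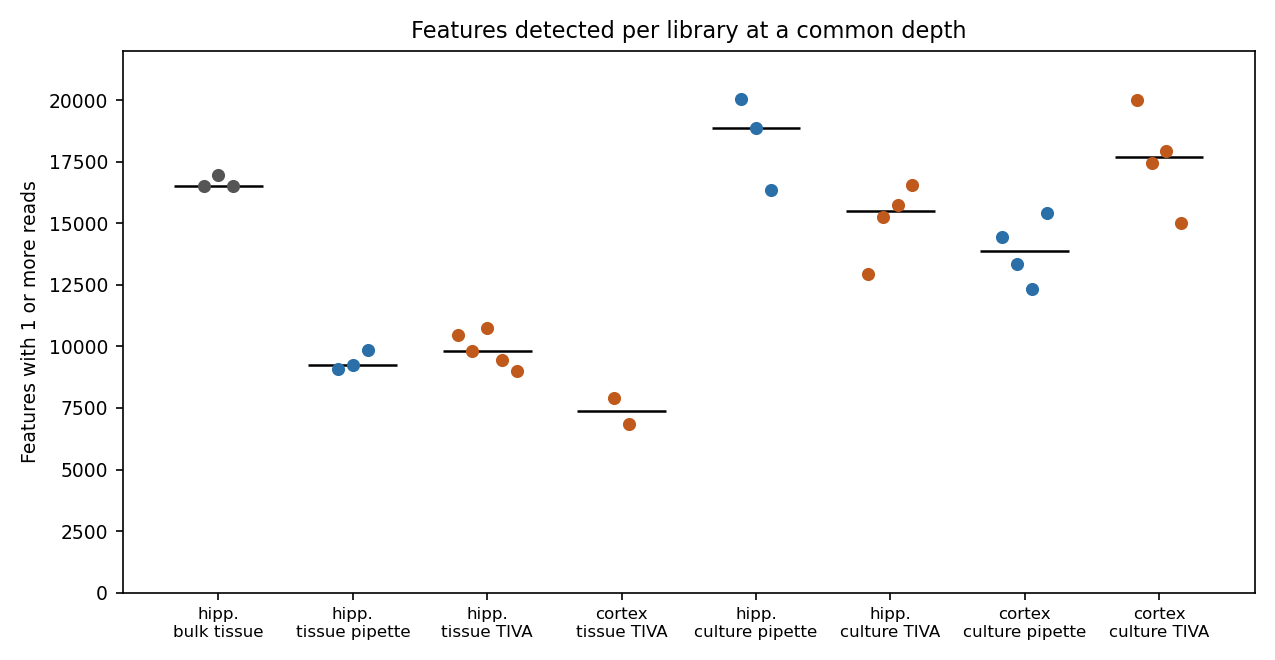
Each point is 1 library thinned to 5.30 M reads, the vertical axis counts features with 1 or more reads, and the bars are group medians (grey, bulk; blue, pipette; orange, TIVA). The 10 neurons taken from tissue sit between 6841 and 10765 features, below the 15 cultured neurons and the 3 bulk libraries.

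Libraries of tissue neurons also differed more from each other than those of 3 of the 4 cultured groups did, cultured cortical pipette neurons being the exception. Among hippocampal tissue TIVA neurons a median of 9.39% of the features at 50 CPM or more in a cell were below 1 CPM in another cell (3.80% to 16.3% over 20 ordered pairs). The share was 10.96% among hippocampal tissue pipette neurons (7.12% to 13.6%), and 15.0% and 27.8% in the 2 directions between the cortical tissue neurons. Cultured cortical pipette neurons had a median share of 6.83% (4.74% to 12.5%). In the other cultured groups nearly every such feature was found in the next library as well: the median was 0.180% in hippocampal pipette neurons (0% to 1.203%, and 0.601% without the first library) and 0% in both TIVA groups, with a highest pair of 0.371% in hippocampus and 0.219% in cortex. Bulk libraries had a median of 0.0385% (0% to 0.0791%). With an on limit of 20 CPM the medians were 15.3% in hippocampal tissue TIVA, 16.6% in hippocampal tissue pipette, 25.4% in cortical tissue TIVA and 11.5% in cultured cortical pipette neurons, 0.634% in cultured hippocampal pipette neurons, 0.165% and 0.175% in cultured hippocampal and cortical TIVA neurons and 0.0716% in bulk tissue. Correlations gave the same division, with within-group medians of 0.666 or less in the 3 tissue groups of single neurons and in cultured cortical pipette neurons, and 0.836 or more in the other 4 groups. The groups with high on-off shares also had the lowest medians of features detected, 13891 or less against 15505 or more. Transcripts lost at capture or amplification would give the same pattern and cannot be told apart from differences between cells here.

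**Figure D2:**
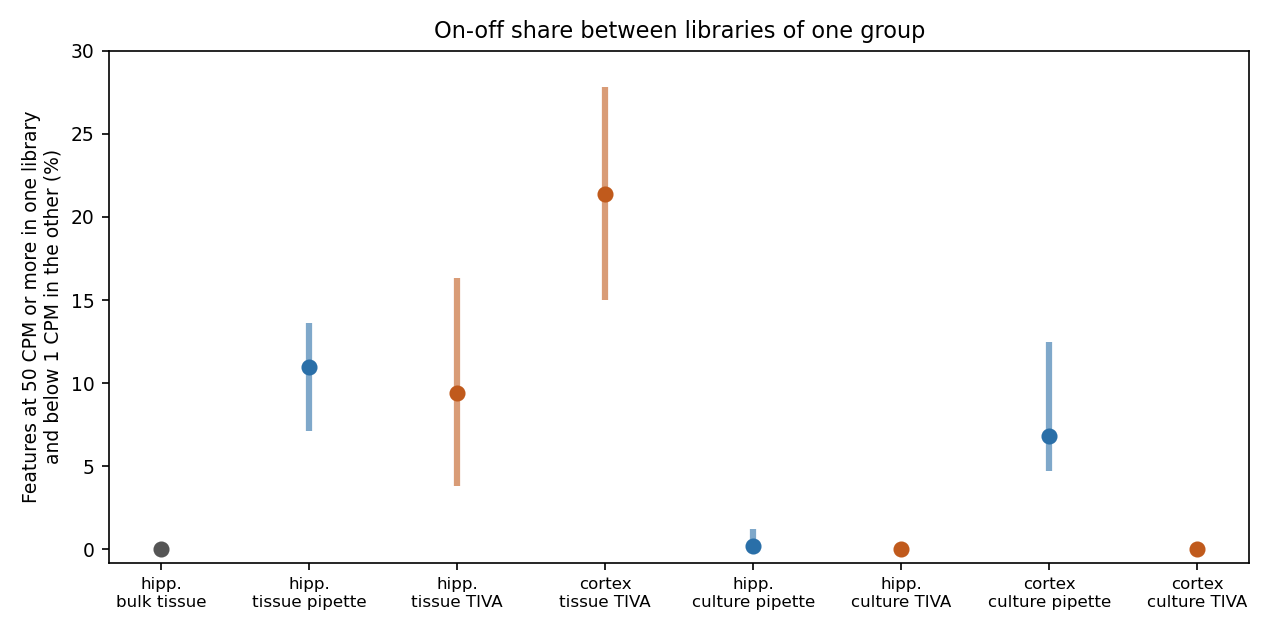
The vertical axis gives the percentage of features at 50 CPM or more in a library that lay below 1 CPM in another library of its group, at the common depth. Points are medians over ordered pairs and lines run from the lowest to the highest pair, with cortical tissue TIVA neurons up to 27.8% and bulk tissue up to 0.0791%.

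The first question was whether TIVA and pipette gave the same transcriptome from cultured hippocampal neurons. The balance of features differed: a median of 53.5% of the reads of a TIVA library went to its 50 most abundant features (25.2% to 66.6%, n = 4), against 15.4% by pipette (14.2% to 18.3%, n = 3). The feature uc009vex.1 alone took a mean over libraries of 11.999% of reads by TIVA (3.56% to 19.97%) and 0.0189% by pipette (0.0108% to 0.0319%). For uc009vev.1 these means were 2.31% (1.63% to 2.76%) and 0.0213% (0.00346% to 0.0485%). Both features were selected partly as high in these cultured TIVA libraries, which favours this contrast. By contrast, uc009jmk.1:uc009jml.1 had a mean of 219 CPM by TIVA (SD 41.3) and 400.2 CPM by pipette (SD 158), with overlapping ranges. The TIVA minus pipette difference in median features detected was −3348, or −2095.5 without the first pipette library and −1611.5 at 10 CPM or more. At 50 CPM or more it was −1369, and 280.0 with CPM taken over the reads outside the 50 most abundant features. The TIVA range of 12953 to 16550 overlapped the pipette range of 16348 to 20035. Correlations were 0.836 within TIVA, 0.902 within pipette and 0.782 between them, a gap of 0.0868. Reads outside features made up 23.5% of all counted reads by TIVA and 67.5% by pipette, where the 3 libraries ranged from 31.5% to 75.3%.

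In cultured cortical neurons the same features set the methods apart. The 50 most abundant features took 40.6% of TIVA reads (24.5% to 61.5%, n = 4) and 18.2% of pipette reads (13.9% to 19.4%, n = 4), and uc009vex.1 averaged 6.85% (2.28% to 11.1%) against 0.424% (0.129% to 0.785%). The mean level of uc009vev.1 was 1.74% (1.08% to 2.44%) against 0.248% (0.0561% to 0.440%). Here the TIVA libraries held more features, by 3784.5 between medians, with overlapping ranges of 15025 to 19987 and 12340 to 15432, and the difference was 369.5 at 10 CPM or more, −800.0 at 50 CPM or more, and 115.5 at that limit with CPM taken over the reads outside the 50 most abundant features. TIVA libraries were much more alike, at r = 0.877 within the group (0.830 to 0.913) against 0.617 among pipette neurons (0.589 to 0.643) and 0.643 between the methods. Across 10584 features the TIVA minus pipette differences in cortex and in hippocampus were correlated at r = 0.490. The no-feature share was 55.3% by TIVA and 68.7% by pipette.

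In hippocampal tissue the order of these features was opposite. Both were selected partly as low in the hippocampal tissue TIVA neurons, which favours this order. The 5 TIVA neurons had a mean of 726 CPM of uc009vex.1 (284 to 1347) and the 3 pipette neurons 2554 CPM (2024 to 3409). For uc009vev.1 the means were 242 CPM (137 to 375) and 3813 CPM (2808 to 4741). The other named features had overlapping levels, with uc009jmk.1:uc009jml.1 at 3854 CPM by TIVA (SD 1324) and 2336 by pipette (SD 1499), and uc008lrl.1:uc008lrm.1 at 673 (SD 246) and 812 (SD 454). Medians of features detected differed by 591 at the common depth, less than the SD over TIVA neurons, and by 1616 before thinning. Without a library the difference lay between 288.5, without the first pipette neuron, and 919, without the fourth or the fifth TIVA neuron. The 50 most abundant features took 17.8% of reads by TIVA and 22.3% by pipette. Correlations were 0.666 within TIVA, 0.656 within pipette and 0.618 between them. Across features, the TIVA minus pipette difference in tissue was nearly unrelated to that in cultured hippocampus (r = −0.0215 over 9449 features) and to that in cultured cortex (r = 0.00793 over 9481 features). The first of these values became 0.0282 with summed counts and 0.0161 without the fifth tissue TIVA neuron. The protocol text of the pipette neurons describes TIVA capture, so their means of collection rests on the source name.

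Tissue and cultured hippocampal neurons, both captured by TIVA, were compared to ask how the setting alters a neuron's transcriptome. The tag dose, loading time and laser power differed along with the setting. By the rule for named features, those with the highest levels in tissue relative to culture were uc009jmk.1:uc009jml.1 and uc008lrl.1:uc008lrm.1. The first averaged 3854 CPM in tissue (2258 to 5559, n = 5) and 219 CPM in culture (167 to 263, n = 4), 17.6-fold higher and a log2 difference of 4.02. Its summed counts were 537974 reads, or 3910.0 CPM (3899.6 to 3920.5), in tissue and 15994 reads, or 209 CPM (205 to 212), in culture. The second averaged 673 CPM (237 to 807) against 42.3 CPM (25.5 to 82.7), 15.9-fold higher and a log2 difference of 3.70. In the other direction, uc009vex.1 averaged 119991 CPM in culture (SD 74254) and 726 CPM in tissue (SD 417), a log2 difference of −7.27, and uc009vev.1 23099 CPM (SD 4999.8) and 242 CPM (SD 113), a log2 difference of −6.60. Leaving out any library kept these log2 differences within 3.87 to 4.19, 3.56 to 4.04, −7.76 to −6.93 and −6.78 to −6.44.

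The tissue TIVA neurons held fewer features than the cultured ones, with a difference of medians of −5683, a ratio of 0.633, and no overlap. Counted at 10 CPM or more the difference was −1134.5 and the ranges overlapped, at 5855 to 7325 in tissue and 6505 to 8219 in culture. At 50 CPM or more the order was opposite, with 3819 features in tissue (3699 to 3887) and 2501 in culture (1703 to 3498), a difference of 1318, or −428 over the reads outside the 50 most abundant features. Reads were concentrated differently, since the 50 most abundant features took 17.8% in tissue and 53.5% in culture. The median log2 difference over the 10897 measured features was 0.12, and it was −0.08 with TMM, 0.23 with DESeq2 and −0.42 with scaling that left out the 50 most abundant features. The 4 named differences kept their direction under each of these scalings, which shows little because they were far larger than such shifts. Other comparisons moved by more than 0.1 as well, with the cultured hippocampal TIVA minus pipette median at −0.45 by library total and 0.11 with TMM.

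Among pipette neurons of the hippocampus the contrast of tissue with culture was wider for detection. The difference of medians was −9622, a ratio of 0.490, and −3493 at 10 CPM or more, with lower values in every tissue neuron on both counts. At 50 CPM or more it was −671, and −766 with CPM taken over the reads outside the 50 most abundant features. The features higher in tissue TIVA neurons were higher here too: uc009jmk.1:uc009jml.1 averaged 2336 CPM (667 to 3567) against 400.2 CPM (250 to 565), and uc008lrl.1:uc008lrm.1 812 CPM (457 to 1323) against 97.6 CPM (82.2 to 113). The features lower in tissue TIVA neurons were higher in tissue pipette neurons, uc009vex.1 at 2554 CPM (2024 to 3409) against 189 CPM (108 to 319) and uc009vev.1 at 3813 CPM (2808 to 4741) against 213 CPM (34.6 to 485). Over 9851 features the tissue minus culture differences by pipette and by TIVA were correlated at r = 0.147, and at 0.24996 with a pseudocount of 1 CPM and 0.231 with DESeq2 scaling. The no-feature share was 18.9% in tissue (15.8% to 30.3%) and 67.5% in culture (31.5% to 75.3%), so scattered reads in the cultured libraries stay open as a cause of the difference in detection.

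Cortical TIVA neurons held fewer features in tissue (6841 and 7886) than in culture (15025 to 19987), a difference of medians of −10312, or −4253.5 at 10 CPM or more. At 50 CPM or more it was −816.5, and −1904.5 with CPM taken over the reads outside the 50 most abundant features. The feature uc009vex.1 was at 9260 and 9109 CPM in tissue and at 22845 to 111434 CPM in culture, and uc009vev.1 at 3324 and 396 CPM against 10804 to 24413 CPM. In contrast to hippocampus, uc008lrl.1:uc008lrm.1 was low in cortical tissue, at 7.22 CPM and at 0 reads, which allows up to 0.567 CPM, against 14.1 to 49.5 CPM in culture. The tissue minus culture differences of cortical and hippocampal TIVA neurons were correlated at r = 0.328 over 9796 features, a relation examined after seeing the data. The no-feature share was 18.8% and 17.6% in the cortical tissue neurons and 43.4% to 67.5% in culture, so scattered reads in the cultured libraries stay open as a cause. Only 2 cortical tissue neurons stood behind the tissue values.

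**Figure D3:**
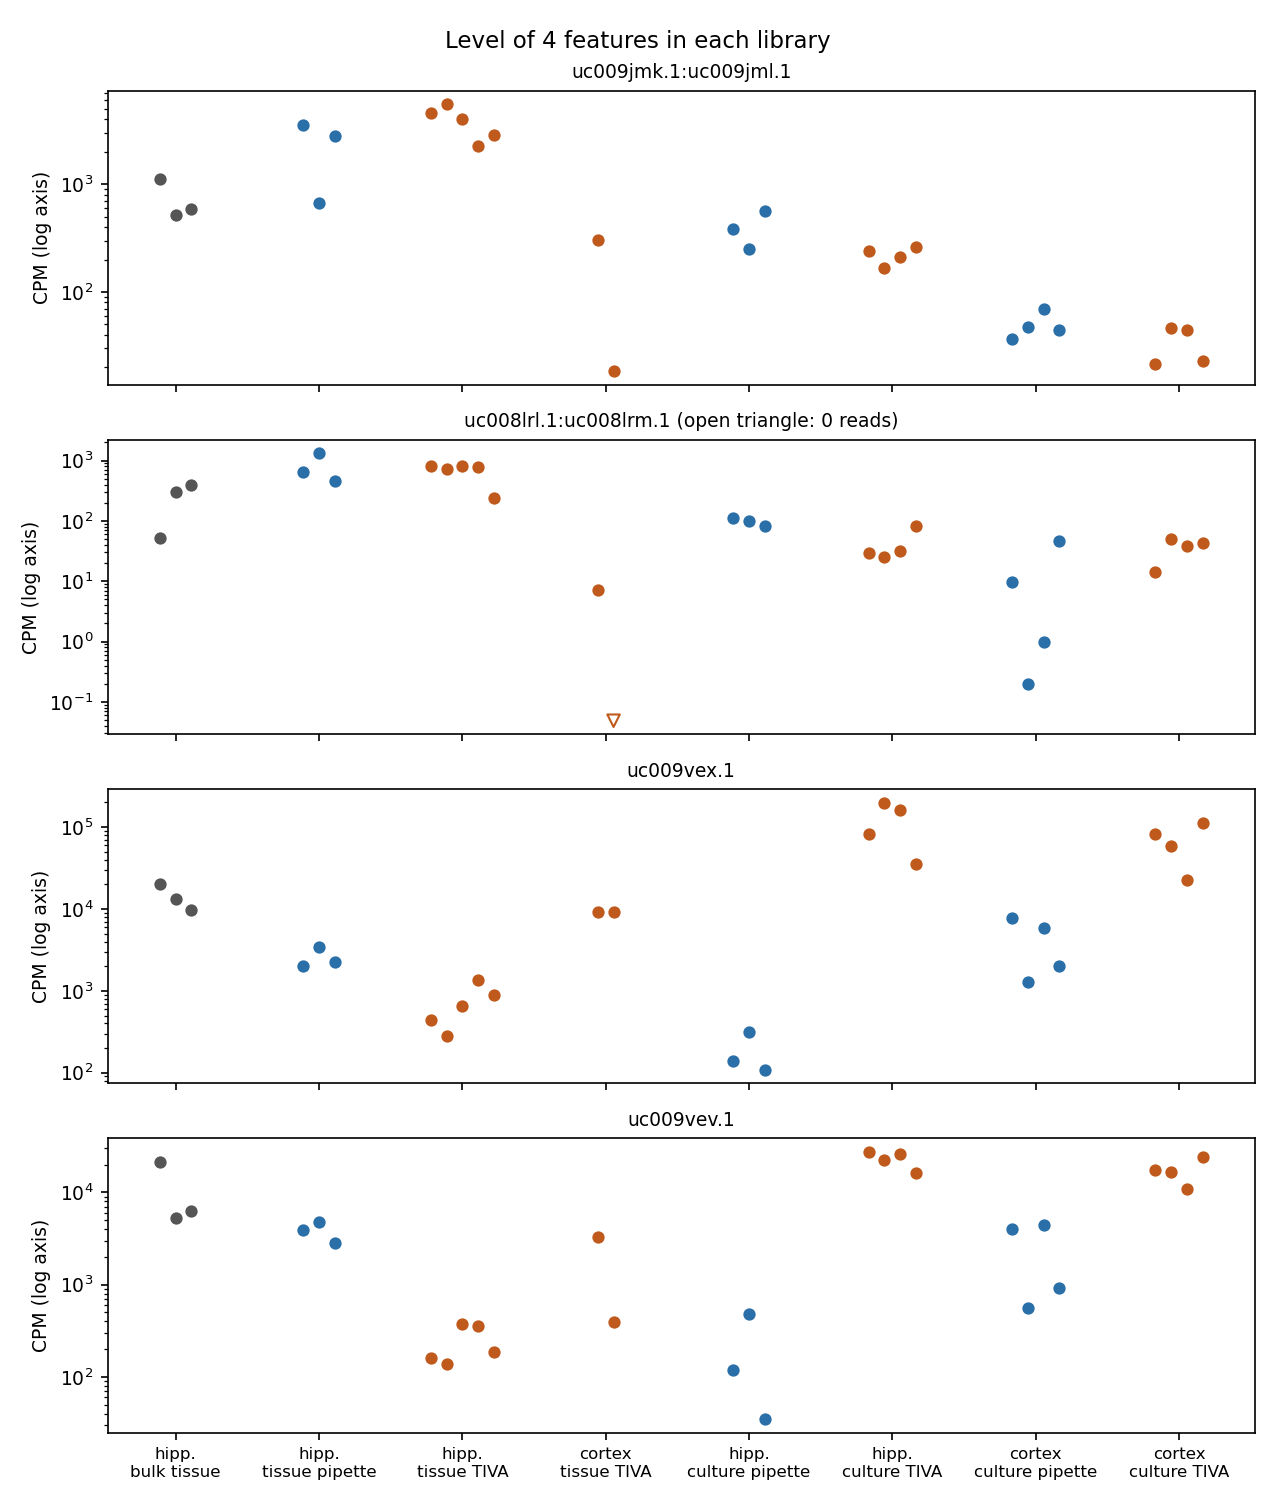
CPM on a log axis for the 4 named features in each of the 28 libraries (grey, bulk; blue, pipette; orange, TIVA); the open triangle, placed below the lowest value, marks a library with 0 reads. In uc009vex.1 the 8 cultured TIVA libraries lie between 22845 and 199719 CPM and the 5 hippocampal tissue TIVA neurons between 284 and 1347 CPM.

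Single hippocampal neurons were set against bulk hippocampus to ask what a single cell lacks of the whole tissue. The difference of medians from bulk tissue was −6706 features for TIVA neurons and −7297 for pipette neurons, with no overlap between either group and bulk. At 10 CPM or more these were −2632 and −3379, and at 50 CPM or more 43 and −577, or −263 and −881 with CPM taken over the reads outside the 50 most abundant features. Of the 2565 features at 50 CPM or more in all bulk libraries, a median of 5.03% were below 1 CPM in a TIVA neuron (1.33% to 6.39%) and 5.07% in a pipette neuron (2.69% to 6.00%). Features at 50 CPM or more in a neuron were nearly all found in bulk tissue, since a median of 0.0784% of them in TIVA neurons and 0.157% in pipette neurons were below 1 CPM in every bulk library. Relative to bulk tissue, uc009jmk.1:uc009jml.1 was higher in TIVA neurons (mean 3854 against 740.02 CPM, 5.21-fold, ranges apart), and its pipette range of 667 to 3567 CPM overlapped the bulk range of 519 to 1117. Levels of uc009vex.1 were lower, at 726 CPM in TIVA neurons and 2554 in pipette neurons against 14384 in bulk tissue (9588 to 20342), and so were those of uc009vev.1, at 242 and 3813 against 10909.7 (5298 to 21182). All these features were selected partly on the hippocampal tissue TIVA values, which favours their TIVA contrasts with bulk tissue. Median correlation with bulk was 0.687 for both kinds of neuron, against 0.893 between bulk libraries. The TIVA minus bulk and pipette minus bulk differences were correlated at r = 0.478 over 10762 features, and 100 simulations of unchanged groups gave 0.201. The covariance was 0.366 against a simulated 0.0746, a difference of 0.292. The 3 bulk libraries could not be split into separate references of 2 or more libraries each, so part of the correlation above the simulated value may come from the shared reference, which the difference of covariances subtracts.

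Cultured TIVA libraries resembled bulk tissue more than tissue neurons did. Their median correlations with bulk libraries were 0.852 in hippocampus and 0.846 in cortex, and a median of 0.0975% and 0.117% of the bulk features were missing from them. Cultured pipette neurons had 0.764 in hippocampus and 0.660 in cortex, with 0.234% and 2.48% of the bulk features missing. Of the 28 libraries, 12 were closest to their own group, among them all 3 bulk libraries and all 3 cultured hippocampal pipette neurons. All 3 hippocampal tissue pipette neurons, both cortical tissue neurons and 3 of the 5 hippocampal tissue TIVA neurons were closest to bulk tissue.

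**Figure D4:**
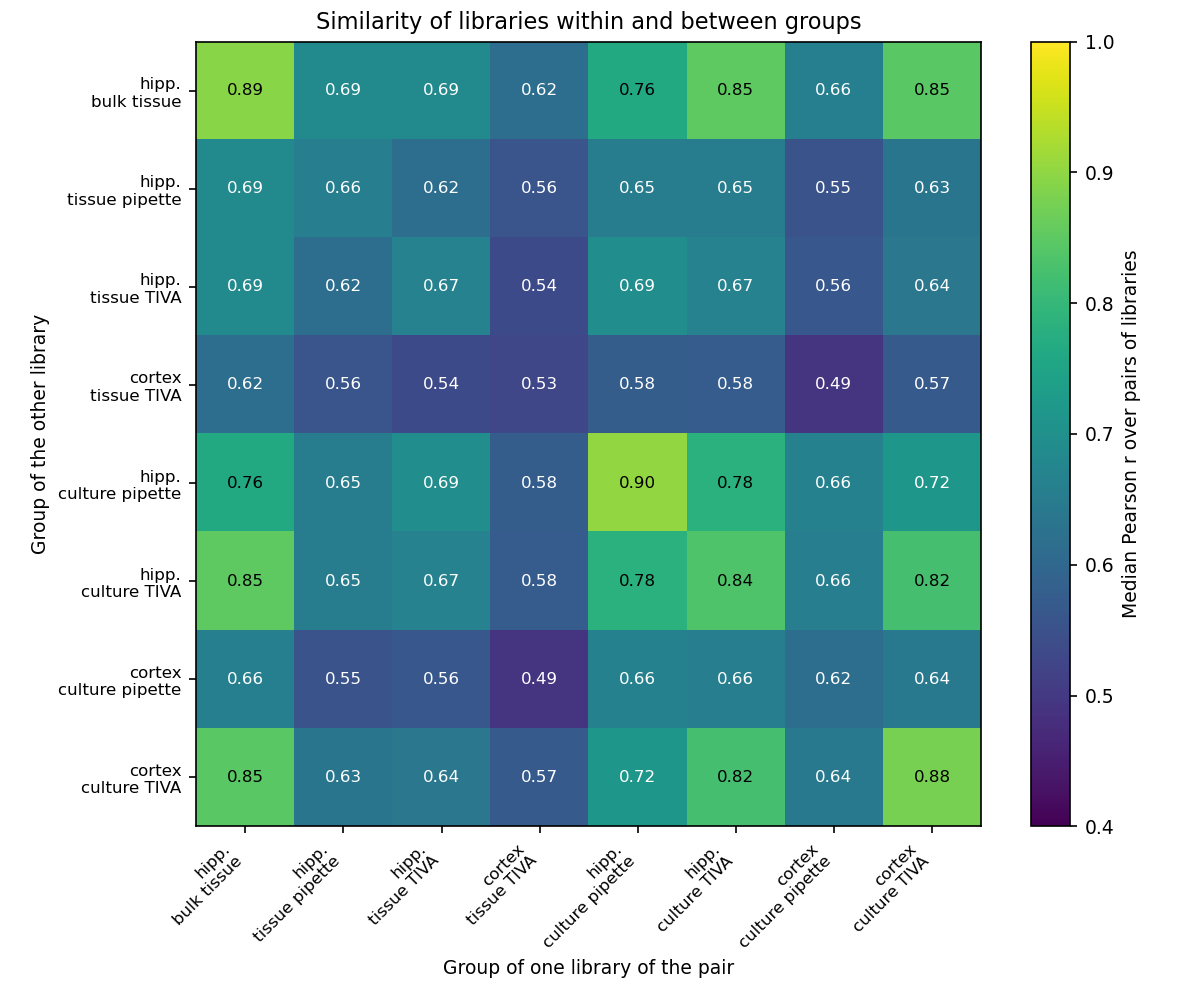
Colour and numbers give the median Pearson correlation of log2(CPM + 10) across 10694 features over pairs of libraries, within groups on the diagonal and between groups elsewhere. Cultured TIVA libraries reach 0.85 with bulk tissue, and cortical tissue TIVA neurons reach at most 0.62 with any group.

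Region was compared within each kind of library. Cultured TIVA neurons of cortex and hippocampus were correlated at r = 0.823 with a gap of 0.0332, less than the pooled SD of 0.0478 over pairs within the groups, and 0.0189 without the first cortical library. Cortex held 2170.5 more features between medians, or 822 more at 10 CPM or more, with overlapping ranges. The difference was 660.0 at 50 CPM or more, and −19.5 with CPM taken over the reads outside the 50 most abundant features. The no-feature share was 55.3% in cortex and 23.5% in hippocampus. In these neurons uc009jmk.1:uc009jml.1 was at 33.7 CPM in cortex (21.6 to 45.9) and 219 CPM in hippocampus (167 to 263). That feature was also lower in cortex among cultured pipette neurons, at 49.2 CPM (36.4 to 69.3) against 400.2 CPM (250 to 565), and among tissue TIVA neurons, at 304 and 18.3 CPM against 2258 to 5559 CPM. Both this feature and the next were selected partly as high in those hippocampal tissue TIVA neurons, which favours the tissue contrast. The feature uc008lrl.1:uc008lrm.1 followed it in pipette neurons, at 14.2 CPM (0.195 to 46.1) against 97.6 CPM (82.2 to 113), and in tissue, while its cultured TIVA ranges overlapped. Cultured cortical pipette neurons held fewer features than hippocampal ones (a difference of −4962 without overlap, −1159 at 10 CPM or more and 91 at 50 CPM or more). Both groups were correlated at 0.664 with a gap of 0.0957. That gap came from hippocampus alone: the within-group median was 0.902 there and 0.617 in cortex, below the correlation between regions. Of the 4 cortical pipette libraries, 0 were closest to their own group. Cortical tissue TIVA neurons also held fewer features than hippocampal ones (−2458.5, without overlap, and −3597.5 before thinning), at depths of 5.30 and 7.89 M reads against 24.1 to 33.4 M before thinning, and r was 0.535 between the groups. The cortex minus hippocampus differences of cultured TIVA and cultured pipette neurons were correlated at r = 0.235 over 10131 features.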

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

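The tests of growth in culture, of TIVA capture itself, of cells as in bulk tissue and of the features below 10 CPM were chosen only after the result was seen. The counts at 10 CPM or more and without the 50 most abundant features were added after the data were seen, before those counts were made, and the counts at 50 CPM or more were added last. None of the differences between comparisons given here was tested. In 44 sets of 4 or 5 libraries, 3 single libraries stood far from the others, and chance gives about 1 in 20. Of 110 pairings of a measure with a pair of comparisons, 15 had every library on opposite sides. These are not independent: the contrast of capture methods between hippocampal culture and tissue is the contrast of settings between hippocampal TIVA and pipette neurons with its sign turned, and the named features were chosen on a comparison that enters it. No chance value was computed for them.

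Hippocampal tissue TIVA neurons held fewer features than cultured ones. Depth points the other way, since the tissue libraries had the higher median of assigned reads, 26.5 against 20.6 M. At a common depth the difference was −5683 (pooled SD 1151). The 50 most abundant features took 17.8% of reads in tissue and 53.5% in culture. Their use of reads would lower detection in culture, so leaving them out, which gave −6529.5 (SD 1204), could not test that use as a cause. At 10 CPM or more the difference was −1134.5 (SD 769), with overlapping ranges. It turned to 1318 at 50 CPM or more, or −428 over the reads outside the 50 most abundant features. These counts decide nothing on a low-level background of scattered reads in the cultured libraries as the whole cause, since its highest level is not known. Below 10 CPM, medians of 3436 and 8545.5 features differed by −5109.5 (SD 1260). With 5 or more reads at the common depth the difference was −4575.5, at 7471 to 9563 features in tissue and 11493 to 13635 in culture. Features with fewer reads than that therefore do not carry the whole difference. Above that limit such a background cannot be told apart from low expression, because the no-feature shares of both groups overlapped. A true narrowing of the transcriptome in tissue, a lower RNA yield from tissue and a library batch stay open as untested. RNA of several cells in the cultured TIVA libraries stays open as well. The tag dose, loading time and laser power differed with the setting and cannot be told apart from it.

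Cultured cortical TIVA libraries were as alike as bulk libraries, unlike pipette neurons of the same kind of culture. Over features at 100 CPM or more the SD of log2 ratios was at least 0.317 lower in every TIVA pair than in any pipette pair. This does not exclude a low-level background. Such a background would also narrow the ratio of a feature abundant in 1 library of a pair and near absent in the other. The on-off shares of the pipette neurons lay at least 4.52 percentage points above the TIVA ones (SD 2.19 over pipette pairs). Those shares restate the pattern itself, so they decide nothing on growth in culture. In cultured hippocampal pipette neurons the median share was 0.180%. The labels name no culture, so a difference between cultures stays open. A candidate explanation is RNA of several cells in each TIVA library: of 27 features at 20 CPM or more in bulk tissue and below 1 CPM in all 8 hippocampal tissue neurons, 92.6% to 100% were present in cortical TIVA libraries and 25.9% to 51.9% in pipette ones, a gap of 40.7 points. In hippocampal cultures these ranges, 74.1% to 100% by TIVA and 70.4% to 85.2% by pipette, overlapped, so this stays a hypothesis for cortex. Presence was counted from 1 CPM, and the cortical TIVA libraries held more features in general, with medians of 17675.5 against 13891. A low-level background would raise such features as well, so the 27 features do not single out RNA of several cells. Carry-over between libraries and a library batch were not tested.

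The feature uc009vex.1 was far higher by TIVA than by pipette in both cultures. In hippocampal tissue the highest TIVA minus the lowest pipette value was −678 CPM, less than the SD of 747 CPM over pipette neurons. It decides nothing on TIVA capture itself, also because the feature was selected partly on those tissue TIVA values and the protocol text of the pipette neurons describes TIVA. The cortical culture mean lay 54107 CPM above the bulk mean (pooled SD 29173) in libraries the selection did not use. This argues against a mix of cells at the levels of bulk hippocampus as the whole cause of that mean. Bulk tissue was not cultured, so cells in its proportions with other levels in culture stay open. The hippocampal culture mean lay 105607 CPM above the bulk mean (SD 57621), which decides nothing because the feature was selected on those libraries. For the third cortical library, the lowest, even a mix at bulk levels stays open. That library lay 2503 CPM above the highest bulk library, and the SD over bulk libraries was 5470.3 CPM. Bulk cortex is not among the groups, so cells in its proportions stay open for cortical cultures. The tag dose, laser power and loading time of cultured TIVA, cells of a kind more common in culture than in tissue, reads shared with near-identical copies and a library batch stay open as untested.

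In uc009vex.1 the TIVA minus pipette difference of medians was 122203 CPM in cultured hippocampus, 65931 CPM in cultured cortex and −1574 CPM in hippocampal tissue, so that the cultures stood apart from tissue by 123777 and 67505 CPM. Its tissue minus culture difference was −121687 CPM for hippocampal TIVA, 2089.9 for hippocampal pipette and −60659 for cortical TIVA neurons, so that these stood apart by −123777 CPM, the first value above with its sign turned, and by 62749 CPM. For uc009vev.1 the corresponding values between capture methods were 27862 and 18334 CPM, and between settings −27862, again the first with its sign turned, and 19015 CPM. For uc008lrl.1:uc008lrm.1 the tissue minus culture difference of cortical TIVA neurons was −37.1 CPM, which stood 801 CPM from that of hippocampal TIVA and 593 CPM from that of hippocampal pipette neurons.

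The reads taken by the 50 most abundant features were higher by TIVA in culture and lower by TIVA in tissue, a contrast of 42.6 percentage points for hippocampal and 27.0 for cortical cultures, and the tissue minus culture difference of TIVA neurons stood −42.6 points from that of pipette neurons, which is the first contrast with its sign turned. The share of reads on features with a single identifier was 25.2 points higher by TIVA in hippocampal culture, 16.6 in cortical culture and −6.79 in tissue, contrasts of 32.0 and 23.4 points.

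The third cultured cortical pipette neuron had 6860 features at 10 CPM or more, against 7649 to 7800 in the others. The level of uc008lrl.1:uc008lrm.1 was 82.7 CPM in the fourth cultured hippocampal TIVA library, against 25.5 to 31.5 CPM in the others, and 237 CPM in the fifth hippocampal tissue TIVA neuron, against 728 to 807 CPM. Reads outside every feature had median shares of 68.7% in cultured cortical pipette, 55.3% in cultured cortical TIVA and 67.5% in cultured hippocampal pipette libraries, and every library of these groups lay above the highest bulk share of 30.5%.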

How the results depend on the processing

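Detection at 10 or 50 CPM or more, detection without the 50 most abundant features, and the relations between cortical and hippocampal tissue minus culture differences and between the region differences were chosen only after the data were seen. Differences in features detected kept their direction under every alternative run except the counts at 50 CPM or more. No paired analysis was possible because replicate numbers only follow record order and no test was run. The alternatives planned for gene lists and marker shares were not run, since the identifiers carry no symbols. Leaving a library out of the 2 cortical tissue neurons leaves no pair, so the on-off share there has no such value. Where no cause is named below, the cause was not tested.

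Counted at 10 CPM or more, which removes low features by construction, the differences in features were −1611.5 (cultured hippocampus, TIVA minus pipette), 369.5 (cultured cortex, TIVA minus pipette), −1134.5, −3493 and −4253.5 (tissue minus culture for hippocampal TIVA, hippocampal pipette and cortical TIVA), −2632 and −3379 (TIVA and pipette neurons minus bulk) and −1159 (cortex minus hippocampus, cultured pipette). With 5 or more reads they were −7732 (hippocampal pipette) and −8474 (cortical TIVA) for tissue minus culture and −5600.0 and −6443 for neurons minus bulk. Unthinned, where depth differs, they were 1616 (tissue, TIVA minus pipette), −7387 and −9003 (neurons minus bulk) and −3597.5 (tissue TIVA, cortex minus hippocampus). At 50 CPM or more, tissue minus culture by TIVA in hippocampus (1318), TIVA minus pipette in cultured cortex (−800.0), hippocampal tissue TIVA minus bulk (43) and cortex minus hippocampus by cultured pipette (91) took the opposite sign. Others beyond 1 SD were −1369 (cultured hippocampus, TIVA minus pipette), −671 and −816.5 (tissue minus culture, hippocampal pipette and cortical TIVA), −577 (tissue pipette minus bulk) and −1474.5 (tissue TIVA, cortex minus hippocampus). With CPM over the reads outside the 50 most abundant features, TIVA minus pipette in cultured hippocampus (280.0), cortex minus hippocampus by cultured TIVA (−19.5) and by cultured pipette (145) took the opposite sign. Others beyond 1 SD were 115.5 (cultured cortex, TIVA minus pipette), −428, −766 and −1904.5 (tissue minus culture for hippocampal TIVA, hippocampal pipette and cortical TIVA), −263 and −881 (TIVA and pipette neurons minus bulk) and −1496 (tissue TIVA, cortex minus hippocampus). The other 42 values stayed within 1 SD, as did all 80 with a library left out, among them the 288.5 to 919 of hippocampal tissue TIVA minus pipette.

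With an on limit of 20 CPM, which admits lower features, the on-off share was 11.5% in cultured cortical pipette, 0.175% in cultured cortical TIVA, 0.165% in cultured hippocampal TIVA, 15.3% in hippocampal tissue TIVA and 16.6% in hippocampal tissue pipette neurons. In cultured hippocampal pipette neurons it was 0.634%, within 1 SD. With a library left out it ran from 0% to 0.0724% in bulk tissue and from 0.129% to 0.601% in cultured hippocampal pipette neurons. Over features of 20 CPM or more, the correlation gap was 0.139 between capture methods in cultured cortex, 0.177 between tissue and culture by pipette and 0.127 between regions by cultured pipette. The last ran from 0.0833 to 0.124 with a library left out, and the gap between regions by cultured TIVA from 0.0189, without the first cortical library, to 0.0448. The 30 other values of the gap stayed within 1 SD.

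Among correlations across features, tissue minus culture by TIVA against by pipette gave 0.24996 and 0.106 with pseudocounts of 1 and 50 CPM, 0.192 with TMM, 0.231 with DESeq2, 0.0988 without a filter, 0.174 with a filter of 20 CPM, 0.173 with medians, and 0.122 to 0.178 with a library left out. TIVA minus pipette in cultured cortex against cultured hippocampus gave 0.451 and 0.529 with those pseudocounts, 0.458 without a filter, 0.528 at 20 CPM, and 0.407 to 0.518 with a library left out. Tissue against cultured hippocampus for that difference gave −0.0516 without a filter, −0.00166 at 20 CPM and, with the opposite sign, 0.0282 with summed counts. It ran from −0.0558 to 0.0161 with a library left out, and the 0.0161 is without the fifth hippocampal tissue TIVA neuron. Tissue against cultured cortex gave 0.0226 with DESeq2, −0.00584 without a filter, 0.0216 at 20 CPM, −0.0183 with medians, 0.0345 with summed counts, and −0.0137 to 0.0352 with a library left out, so neither relation has a settled sign. Both neuron minus bulk differences gave 0.525 at a pseudocount of 1 CPM, 0.523 at 20 CPM, 0.432 with medians, 0.436 with summed counts, and 0.431 to 0.502 with a library left out. Tissue minus culture by TIVA in cortex against hippocampus gave 0.366 at 1 CPM, 0.369 with DESeq2, 0.258 without a filter, 0.386 at 20 CPM, 0.287 with medians, 0.283 with summed counts, and 0.248 to 0.344 with a library left out. Cortex minus hippocampus by TIVA against by pipette gave 0.194 at 1 CPM, 0.183 without a filter, and 0.158 to 0.302 with a library left out.

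Of 32 values of the 4 named differences, 29 stayed within 1 SD, 3 moved by more, and none changed sign. The floor of 0.0508 to 0.567 CPM limits statements on absence to levels above it.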

Other observations

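Of the single neurons, the cortical tissue TIVA neurons lacked the most of the abundant bulk features, with 10.3% and 18.9% of the 2565 below 1 CPM. Cultured cortical pipette neurons had the most features that bulk hippocampus lacked: a median of 1.09% of their features at 50 CPM or more (0.275% to 2.53%) were below 1 CPM in all 3 bulk libraries, against 0% in all 4 cultured cortical TIVA libraries. The bulk libraries come from hippocampus, so for cortical neurons the reference is another region.

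The single most abundant feature of a library took a median of 16.8% of reads in cultured hippocampal TIVA neurons (5.54% to 20.2%) and 13.3% in cultured cortical TIVA neurons (6.62% to 23.2%). It took 7.79% in cortical tissue TIVA neurons, 1.86% in hippocampal tissue TIVA neurons (1.69% to 2.62%) and 1.03% in cultured hippocampal pipette neurons (0.912% to 1.09%). Ambiguous reads, which overlap several features, were highest in cultured hippocampal TIVA libraries, with a median of 9.71% of counted reads (5.79% to 10.9%), followed by bulk tissue at 5.68%, and lowest in cultured hippocampal pipette neurons at 0.821%.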
